A study of Mus musculus with 21 samples.

How the data were processed

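The samples were punches of the nucleus ambiguus taken from frozen brains of male and female mice by the Palkovits technique, in which a needle removes a small region from a thick brain section. Per the labels, 5 wild-type (WT) males, 6 knockout (KO) males, 4 WT females and 6 KO females are analysed here. The genotype label of the KO mice names Chat, and the strain is Ren-aChAT-KO. The design text counts 6 WT males, and the remaining animal was not analysed here. Per the labels' protocols, libraries were made with a low-input, strand-preserving kit for full-length cDNA. The sources name different RNA kits: the design text gives a spin column kit and the sample labels give TRIzol. The labels describe the samples as coming from mice but do not state that each library is a different animal, so the p-values measure the spread between these samples.

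The authors deposited 1 table of whole-number counts per gene and library, not normalized, with the chromosome, start, end, strand and length of each gene. Per the submitters' processing notes, the tools were FastQC, STAR 2.7.10b and featureCounts 2.0.6 on the GRCm39 build; the settings and the gene annotation are not given in the sources used here. The deposited length of all 57187 entries equals end minus start plus 1, so it is the span of a gene and not the length of its exons. Counts of genes that overlap others appear to have been dropped when the authors counted: all 349 protein-coding genes lying inside another gene on the same strand, and all 612 inside a gene on the opposite strand only, had no count in any library, against 16.4% of the 11285 that overlap no gene. A value of 0 for such a gene therefore carries no information. The table also has an entry for Cre, the recombinase carried by the KO strain, which was left out of library sizes and tests and is reported as counts. Of the 57186 other entries, 51880 were given a symbol from a table of gene names and 5306 kept their identifier. Each of the 21 columns matched 1 sample by the label in its description.

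Total counts were 21550304 to 32688943 per library, with a median of 26233798. Reads of polymerase chain reaction products without molecular identifiers are not independent molecules, so limits given for counts of 0 (3 counts per library) cover counting error only. The common dispersion of 0.020 and 17 residual degrees of freedom set the precision of the gene tests.

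Genes were filtered with filterByExpr by group, which left 18092 genes (17664 with a symbol), and scaled by the trimmed mean of M values (TMM). Levels are CPM on TMM-scaled library sizes, as mean ± SD over the libraries of a group. The gene test was the quasi-likelihood F test of edgeR 4.0.16 with robust estimation (R 4.3.3), on 1 fit of all 21 libraries with group as the only term. Fold changes are log2 values, KO minus WT or female minus male, each with its standard error (SE) from the fit. Adjusted p-values are from the Benjamini-Hochberg procedure, with a threshold of 0.05. The comparisons were KO with WT in males, in females and averaged over the sexes, the difference of the female and the male KO effect (the interaction), and females with males in each genotype.

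A fixed set of 41 gene lists (cell types, pathways and complexes of the hindbrain) was tested with camera of limma 3.58.1 on log2 CPM (prior count 2), which compares the genes of a list with all other genes and assumes a preset correlation of 0.01 between them. The same test with a correlation estimated from the data and the fry rotation test, which asks whether the genes of a list move on balance in one direction, are given beside it. Members of a list past the threshold are counted over all genes tested and adjusted over the list alone. The comparisons, tests, lists, alternatives and the rule for naming genes were set before the data were examined; list tests between the sexes were added later.

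Under that rule, Chat, Slc18a3, Slc5a7, Ren1 and Agt were named in each comparison of KO with WT. To these were added up to 10 genes that rose and 10 that fell with the largest change among genes past the threshold, with a mean log2 CPM above 0 and leaving out predicted gene models. Where fewer than 5 passed in a direction, genes with the smallest p were added and named as not passing. Up to 4 members with the smallest p of each list past its test were eligible, as was any member past the threshold adjusted over its list alone. For the interaction the rule took 5 genes per direction, and for the sexes 6 per direction with Xist, Ddx3y, Kdm5d, Uty and Eif2s3y. Predicted gene models and list members of the sex comparisons are named beyond this rule and were chosen after their values were seen.

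Alternatives were other scalings (relative log expression, upper quartile, and library sizes without mitochondrial, haemoglobin and ribosomal RNA genes), no filter and a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, voom with sample weights, surrogate variables from sva 3.50.0, the replicate number or the description number as a block, a fold threshold of 1.2, an adjusted p under 0.1, only the groups compared, and leaving out each library. Added after seeing the data were the mean of the motor neuron list as a covariate, fits without the 3 libraries whose description number is 5274, the ratio of Chat to Slc5a7, list tests without KO female 6, WT male 2, KO female 2, WT male 4 or WT female 1 and 2, and the levels of Chat and Slc5a7 without KO male 6. The description number is a number in the sample labels of unstated meaning. Male libraries carry 5273, 5306 or 5315 and female libraries 5274, 5307 or 5316, so it cannot be told apart from sex and is shared by WT and KO within a sex only in part. No libraries were duplicates: the lowest chi-square per gene between 2 libraries of a group was 5.60 over 46 pairs.

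Near-identical copies of named genes were searched with blastn 2.17.0 among transcript sequences of an older mouse annotation (GENCODE M21), which served for names and sequences only; coordinates are those of the authors' table. The scripts were tested on simulated counts with 200 genes changed by 1.5- or 2-fold. In the simulated male comparison, run on 17875 genes, 57% of the 1.5-fold and 73% of the 2-fold changes were recovered, and 6 of 144 calls were false. For females (17868 genes) the shares were 47% and 77%, for the average (17846 genes) 67% and 88%, and for the interaction (17859 genes) 34% and 67%. For the sexes they were 52% and 76% in WT (17869 genes) and 61% and 75% in KO (17876 genes). False calls were 9 of 144 in females, 8 of 178 in the average, 7 of 110 in the interaction, and 4 of 139 and 3 of 148 between the sexes in WT and KO. The simulated counts were drawn for each gene on its own, without structure shared between libraries, so these rates need not hold for the data. Correlations across libraries and differences of single values were tested by permutation, two-sided. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.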

Results

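RNA was sequenced from punches of the nucleus ambiguus, a column of hindbrain neurons that includes cholinergic motor neurons of the throat and vagal neurons that slow the heart. The mice were wild type (WT) or carried a knockout (KO) of Chat, the gene of the enzyme that makes acetylcholine. By the strain name, the knockout is meant for cells that express renin. The study's title concerns neurons of this nucleus that express renin and are cholinergic. The 21 libraries came from 5 WT males, 6 KO males, 4 WT females and 6 KO females. Each library held 21550304 to 32688943 counts (median 26233798), and 22217 to 23721 genes had at least 1 count. Mitochondrially encoded genes took 2.81% to 7.08% of the counts of a library, and the 10 most abundant genes took 5.54% to 8.77%.

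Cre recombinase, the enzyme that removes marked stretches of DNA, was counted in each KO library and in no WT library. The 6 KO male libraries held 31 to 115 Cre counts (2.20 ± 1.26 CPM, SD, n = 6) and the 6 KO female libraries 27 to 124 (3.05 ± 1.70 CPM, n = 6). All 9 WT libraries held 0 counts, which at a floor of 3 counts per library allows up to 0.119 CPM. The Y-linked helicase gene Ddx3y was at 66.1 ± 4.27 CPM in WT males (n = 5) and 66 ± 4.41 CPM in KO males (n = 6). Ddx3y had 0 counts in WT females and at most 1 count in KO females. Both markers followed the labels in all 21 libraries.

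Chat itself (ENSMUSG00000021919, chromosome 14, 32130160 to 32187946, GRCm39) was not measurably lower in KO punches. Its level was 13.3 ± 3.75 CPM in WT males (n = 5) and 13.3 ± 8.76 CPM in KO males (n = 6), a log2 fold change of -0.00 (SE 0.37, adjusted p = 1). In females it was 20.4 ± 7.74 CPM in WT (n = 4) and 14.8 ± 4.95 CPM in KO (n = 6), a log2 fold change of -0.46 (SE 0.38, adjusted p = 0.993). Averaged over the sexes, the log2 fold change was -0.23 (SE 0.27, adjusted p = 0.95). The labels do not say which part of Chat the allele lacks, and a punch holds more cells than those that express Cre, so Chat counts do not test the deletion. Slc5a7, the choline transporter of cholinergic terminals, was at 29.2 ± 5.56 CPM in WT males and 44.3 ± 27.2 CPM in KO males (log2 fold change 0.60, SE 0.38, adjusted p = 0.782). In females Slc5a7 was at 50.8 ± 19.9 CPM in WT and 48.9 ± 17.5 CPM in KO (-0.06, SE 0.40, adjusted p = 0.997). Slc18a3, the vesicular acetylcholine transporter, lies inside Chat (chromosome 14, 32184395 to 32186807) and had 0 counts in all libraries, like other genes nested in a gene, so its level is unknown. Ren1, the renin gene (chromosome 1, 133278248 to 133288063), had 0 to 5 counts per library and was below the filter. Agt, which encodes the precursor cleaved by renin, was at 102 ± 22.9 CPM in WT males and 75.6 ± 27.5 CPM in KO males (log2 fold change -0.44, SE 0.22, adjusted p = 0.689), and at 72.5 ± 8.01 and 72.9 ± 10.2 CPM in WT and KO females. The 6 tested genes of the cholinergic machinery had a median log2 fold change of 0.07 in the average (camera adjusted p = 0.825; adjusted p = 0.898 with an estimated correlation). The 14 brainstem motor neuron markers had a median of 0.04 (adjusted p = 0.816; adjusted p = 0.898 with an estimated correlation).

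**Figure D1:**
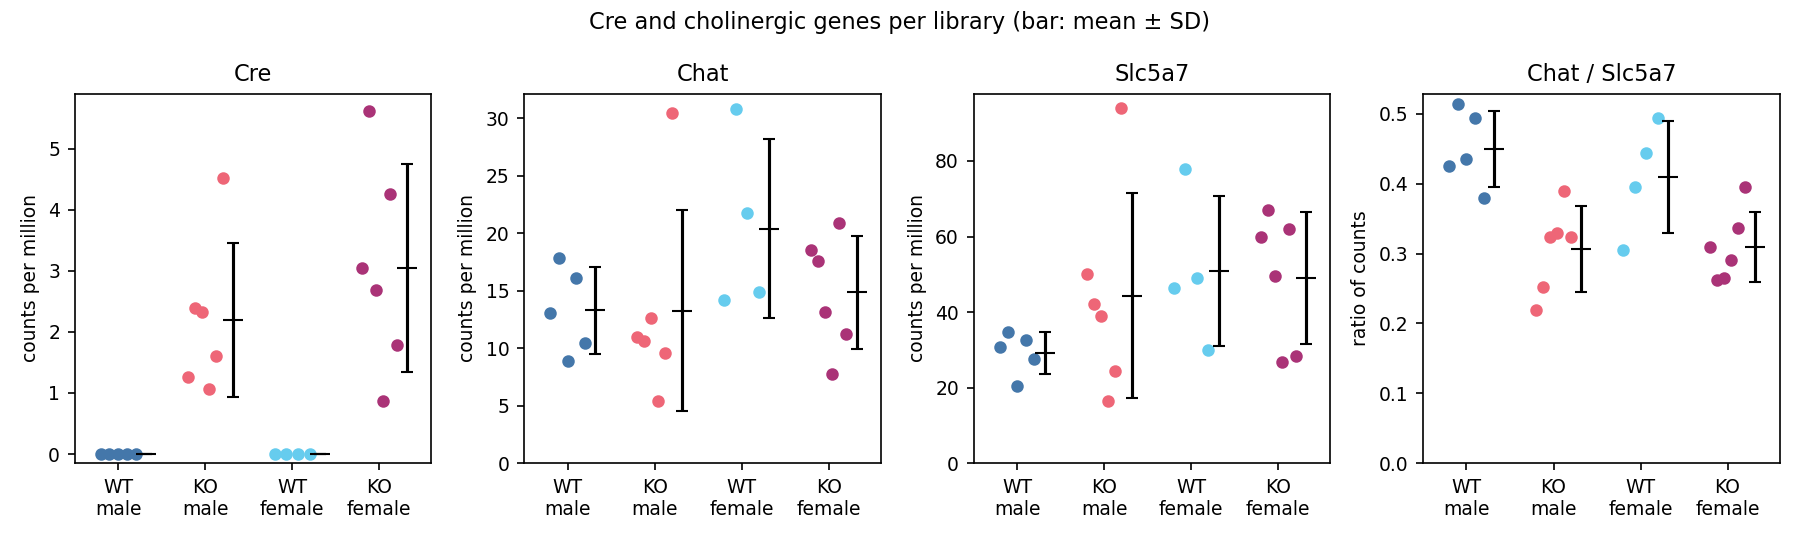
Cre, Chat and Slc5a7 in CPM and the ratio of Chat to Slc5a7 counts (vertical axes) in each library (points) of the 4 groups, with bars for the mean ± SD. Cre is at 0 in the 9 WT libraries, the groups overlap for Chat and Slc5a7, and the ratio averages 0.450 in WT males and 0.306 in KO males, 0.410 in WT females and 0.310 in KO females.

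In males, the comparison of KO with WT asked which transcripts of the punch differ between the genotypes. Every KO library and no WT library held Cre, so effects of Cre, of DNA carried with the Chat allele and of a loss of Chat cannot be told apart. WT male 1 to 4 share a description number with KO male 3 alone. KO male 1 and 2 have a number without WT males, so genotype and number are told apart only in part. In KO males 6 genes rose and 2 fell among 18092 tested, and all 8 are on chromosome 14 or are close copies of genes there. As predicted gene models, 7 of them fall outside the rule for naming and were chosen after their values were seen. Gm6768 rose from 0.704 ± 0.244 CPM in WT males (n = 5) to 7.74 ± 1.05 CPM in KO males (n = 6), a log2 fold change of 3.47 (SE 0.21, adjusted p = 1.15e-11). Its sequence (chromosome 12, 119224713 to 119226590) matches that of Ncoa4, a nuclear receptor coactivator and ferritin receptor gene on chromosome 14 at 31881822 to 31901812, over 1878 bases at 99.9% identity. Gm10020 (chromosome 15, 52341013 to 52341624) rose by a log2 fold change of 4.98 from 0.195 ± 0.120 to 6.12 ± 0.594 CPM. Its closest match is Rpl15, a ribosomal protein gene on chromosome 14 at 4198305 to 4201873, at 99.7% identity. Gm10020 resembles 14 other genes at over 95%, Rpl15 included, so its counts are uncertain too. Gm6123 (chromosome 1, 4841354 to 4842422) rose by 3.17 from 1.33 ± 0.234 to 12 ± 2.58 CPM; it matches Pdhb, a pyruvate dehydrogenase subunit gene on chromosome 14, at 97.0% identity. On chromosome 14 itself, Gm3373 (16727577 to 16751437) rose by 4.17, Gm3411 (16182523 to 16210026) by 2.66 and Gm26630 (16022813 to 16117729) by 2.53. These 3 belong to families of near copies: Gm3373 and Gm3411 each resemble 46 other genes at over 95% identity and Gm26630 resembles 9, so their counts are uncertain. The noncoding gene model Gm48370 (chromosome 14, 13010593 to 13069149) fell from 4.08 ± 0.481 to 1.77 ± 0.585 CPM (log2 fold change -1.19). Duxbl1, a double homeobox gene (chromosome 14, 25979001 to 25990512), fell from 8.52 ± 0.722 to 4.76 ± 1.23 CPM (log2 fold change -0.84, SE 0.16, adjusted p = 0.0334) and resembles 2 other genes at over 95%. For each of the 8 genes, all 6 KO males lay beyond every WT male. With the description number as a block 6 of them passed, and Gm48370 (-1.11) and Duxbl1 (-0.80) did not.

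The genes next in rank in males did not pass the test. Slc6a5, the neuronal glycine transporter, was at 374 ± 31 CPM in WT and 515 ± 59.6 CPM in KO males (log2 fold change 0.46, SE 0.10, adjusted p = 0.0899). Trpm8, a cold-sensitive channel, had a log2 fold change of 0.56 (SE 0.12, adjusted p = 0.0899) and Tacr3, the neurokinin B receptor, of 0.57 (SE 0.12, adjusted p = 0.106). Mpped1 (0.47) and Elfn1, a postsynaptic adhesion protein gene (0.39), were the other genes of smallest p on the higher side, with adjusted p-values of 0.0866 and 0.227. On the lower side were Rhpn2 (-0.51), the Rho exchange factor gene Net1 (-0.50) and Tmem254a (-0.46), with adjusted p-values of 0.0899, 0.105 and 0.109. Gfap, the intermediate filament of astrocytes, was at 187 ± 124 CPM in WT and 42.2 ± 19.3 CPM in KO males (log2 fold change -2.14, SE 0.47, adjusted p = 0.227). Gfap, Enpp6 of immature oligodendrocytes (-0.42), Chrna4, a nicotinic receptor subunit (0.34), and Vim, another intermediate filament (-0.27), did not pass over all genes in this fit and passed adjusted over the list alone, as did Lbx1 (0.51), Foxj1 of ciliated cells (0.28) and Sostdc1 (1.25). DESeq2 called 23 genes, which hold the 8 above and Slc6a5, Trpm8, Tacr3, Mpped1, Elfn1, Rhpn2, Net1, Tmem254a and Gfap; voom called 19, which hold the 8 and Slc6a5, Trpm8, Mpped1, Rhpn2, Net1 and Tmem254a. Gfap also passed in edgeR without robust estimation, and the count was 24 without KO male 3 and 22 with 2 surrogate variables.

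**Figure D2:**
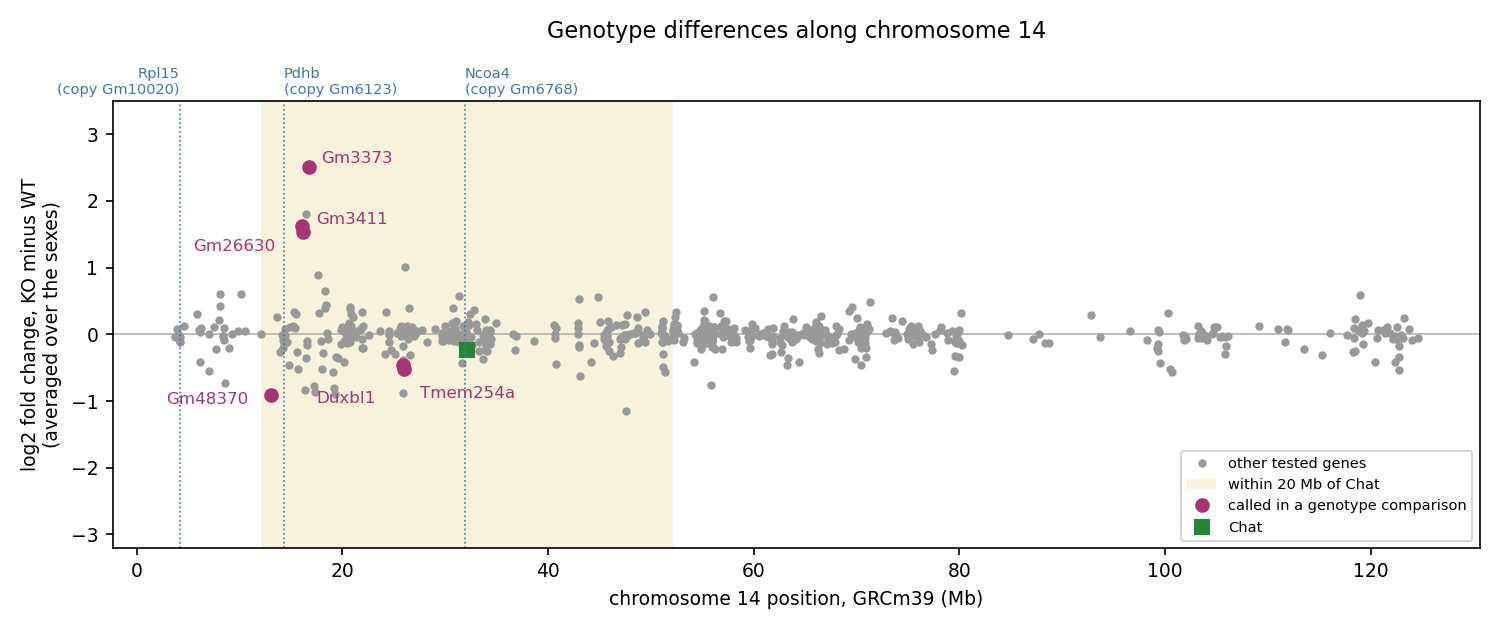
Log2 fold change of KO against WT, averaged over the sexes (vertical axis), of tested genes along chromosome 14 in GRCm39 (horizontal axis, Mb), with the stretch within 20 Mb of Chat shaded, called genes in purple, and dotted lines at Rpl15, Pdhb and Ncoa4, genes with a called copy elsewhere. The 6 genes of this chromosome called in some KO comparison, of which Duxbl1 passed in males only, lie within the shaded stretch.

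Among gene groups, 12 of 41 lists passed camera in males with the preset correlation and 0 passed with an estimated one (smallest adjusted p = 0.0601), where fry called 1. The 21 voltage-gated potassium channel genes stood higher in KO males: 15 had positive changes, 8 of them rose adjusted over the list alone, and the median log2 fold change was 0.16 (adjusted p = 3.79e-05; adjusted p = 0.364 with an estimated correlation). Kcnh1 (0.69, SE 0.19), Kcnc3 (0.35, SE 0.10), Kcnb1 (0.29, SE 0.09) and Kcnd3 (0.36, SE 0.12) had the smallest p, and Kcnab1 (0.42), Kcna4 (0.35), Kcna2 (0.29) and Kcnc1 (0.19) also passed in that way. Markers of glycinergic and GABAergic neurons were higher in 7 of 9 cases (median 0.21, adjusted p = 0.00183; adjusted p = 0.0601 with an estimated correlation; fry adjusted p = 0.00943). Slc6a5, the vesicular transporter gene Slc32a1 (0.24, SE 0.08) and the transcription factor gene Pax2 (0.65, SE 0.20) passed adjusted over that list alone. GABA and glycine receptor genes were higher in 15 of 20 cases, led by Gabra3 (0.27), Gabrb3 (0.21) and Glra1 (0.82) (adjusted p = 0.0018; adjusted p = 0.486 with an estimated correlation). Synaptic vesicle genes were higher in 17 of 24 cases, with Sv2c at 0.34 and Syt2 at 0.25 (adjusted p = 0.00337; adjusted p = 0.486 with an estimated correlation).

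The other 8 lists passing in males were lower in KO. All 9 serotonergic markers (median -0.94) and all 8 catecholaminergic markers (median -0.92) had negative changes, with adjusted p-values of 3.79e-05 and 0.000251 (adjusted p = 0.364 for each with an estimated correlation). WT male 4 lay among the KO males for both lists (means -0.31 and -0.51; other WT males 0.74 to 1.12 and 0.90 to 1.07), and without it the medians were -1.11 and -1.14 (adjusted p = 2.77e-08 and 8.33e-08; adjusted p = 0.155 and 0.111 with an estimated correlation). Tph2, the enzyme of brain serotonin synthesis, was at 20.7 ± 11.2 CPM in WT and 5.38 ± 5.52 CPM in KO males (-1.96, SE 0.90). Th, the first enzyme of dopamine synthesis, had a change of -0.85 (SE 0.44). Ddc, which serves serotonin and dopamine synthesis and is in both lists, passed adjusted over each list alone (-0.94, SE 0.30). Of 73 ribosomal protein genes, 71 had negative changes with a median of -0.10 (adjusted p = 0.0018; adjusted p = 0.906 with an estimated correlation), and 0 passed over all genes or over the list alone. In 27 of 100 splits of the 11 males, the real one included, the ribosomal and potassium channel lists passed in opposite directions. All 11 fibroblast and meningeal markers were lower (median -0.23, adjusted p = 0.00337; adjusted p = 0.215 with an estimated correlation), with Col1a2 at -0.28. WT male 2 stood apart for this list (mean 0.56, other WT males -0.09 to 0.05), and without it the list did not pass (median -0.14, adjusted p = 0.113). Oligodendrocyte markers had a median of -0.09 (Mbp -0.18, Plp1 -0.15; adjusted p = 0.026; adjusted p = 0.779 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.30 (Mrc1 -0.81; adjusted p = 0.0383; adjusted p = 0.364 with an estimated correlation). Glucocorticoid response genes had a median of -0.14 (Per1 -0.33, Sgk1 -0.56; adjusted p = 0.00809; adjusted p = 0.486 with an estimated correlation). For this list KO male 3 had the highest mean of the males (1.12), above WT male 1 to 4 of its description number (0.37 to 0.94). WT male 5 (0.59) lay above the KO males of its number (0.19 to 0.35), so the direction differed between numbers. Neuropeptides had a median of -0.16 with members going both ways, Gal at -1.05 and Vip at 1.46 (adjusted p = 0.0484; adjusted p = 0.364 with an estimated correlation). The count of lists was 7 without WT male 2 and 6 with the description number as a block.

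In females 1 gene passed the same test, again Gm6768, which rose from 0.797 ± 0.150 CPM in WT (n = 4) to 7.91 ± 2.03 CPM in KO (n = 6), a log2 fold change of 3.30 with all 6 KO females above every WT female. The other 5 genes that rose in KO males were as high in WT female 1 and WT female 2 as in KO females; these libraries and KO female 1 share a description number in the labels. Gm10020 was at 5.16 and 5.98 CPM in WT female 1 and 2, against at most 0.464 CPM in the other 7 WT libraries; Gm6123 was at 12.8 and 13.7 CPM against at most 2.02 CPM. Gm6768 was at 0.873 and 0.777 CPM in the same libraries, within the WT range. Without the 3 libraries of that number, 4 genes rose in KO females: Gm6768, Gm10020, Gm6123 and Gm3373. Only WT female 3 and 4 were then left as WT. The rise of Gm10020, Gm6123 and Gm3373 follows from leaving out the WT libraries in which they were high, so it is no separate evidence. The genes of smallest p that did not pass all had an adjusted p of 0.993. Wdfy4, on chromosome 14 at 32681504 to 32907465, had a log2 fold change of 0.77 (SE 0.18), from 1.97 ± 0.321 to 3.36 ± 0.445 CPM. Zfp960 (1.03), the ubiquitin ligase gene Mib2 (0.31), Vars2, a mitochondrial valyl-tRNA synthetase gene (0.43), and Myo15 (0.66) followed. On the lower side were Tmem254a (-0.45, SE 0.11), the interleukin gene Il4 (-0.26), Rab39b (-0.32), Slc25a24 (-0.70) and the leukocyte tetraspanin gene Cd53 (-0.66).

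**Figure D3:**
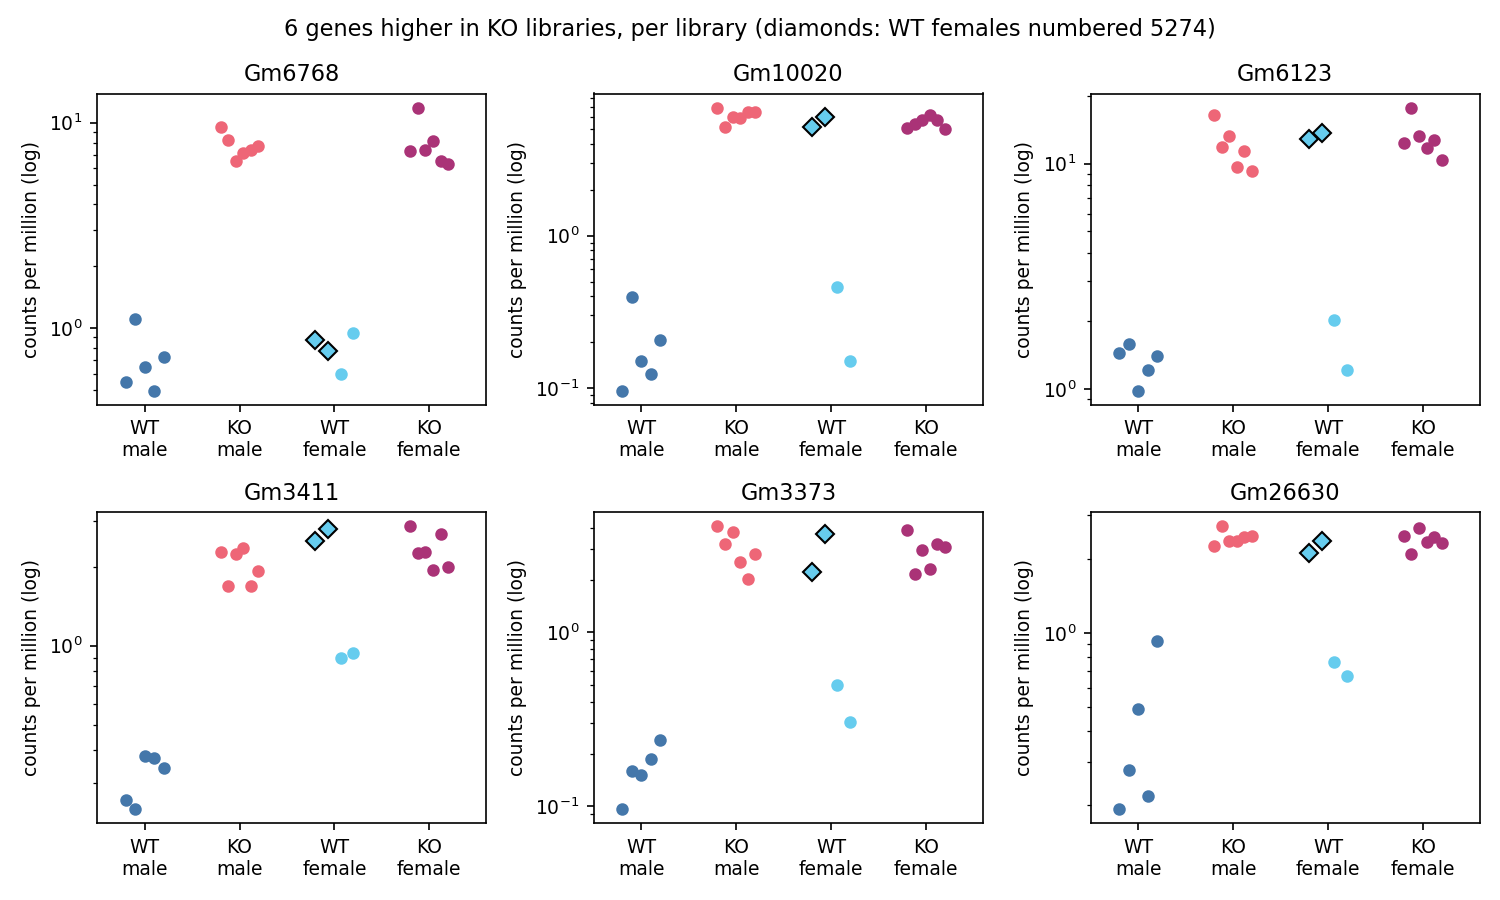
CPM on a log axis (vertical) of 6 genes in each library of the 4 groups, with WT female 1 and 2 as diamonds. Gm6768 separates the 12 KO from the 9 WT libraries, while the diamonds lie among the KO libraries for Gm10020, Gm6123, Gm3411, Gm3373 and Gm26630.

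The 4 lists that passed in females were lower in KO with the preset correlation, and 0 passed with an estimated one or with fry. All 15 mitochondrially encoded genes had negative changes (median -0.30, adjusted p = 8.09e-08; adjusted p = 0.849 with an estimated correlation), with mt-Nd6 at -0.30 (SE 0.10), mt-Atp6 at -0.40 and mt-Co1 at -0.26. The mitochondrial share of counts was 6.24 ± 0.961% in WT females (n = 4) and 5.21 ± 1.34% in KO females (n = 6), where KO female 2 had 2.81% (list mean -1.01, other KO females -0.22 to 0.27). Without it the list had a median of -0.26 with 1 of 15 genes positive (adjusted p = 0.00049; adjusted p = 0.998 with an estimated correlation). WT female 1 and 2 (list means 0.36 and 0.45) stood above WT female 3 and 4 (-0.04 and -0.02), which lay among the KO females, and without WT female 1 and 2 the list did not pass (median -0.08, adjusted p = 0.177). Ribosomal protein genes (70 of 73 lower, median -0.09, Rps25 -0.21) and nuclear oxidative phosphorylation genes (43 of 45 lower, median -0.09, Ndufa7 -0.20) had adjusted p-values of 4.05e-05 and 0.000335 (adjusted p = 0.997 for each with an estimated correlation). Cerebellar neuron markers had a median of -0.13, with Zic2 at -0.28 and Pcp4 at -0.38 (adjusted p = 0.0338; adjusted p = 0.849 with an estimated correlation). Without WT female 1, WT female 2 and KO female 1 together the count was 8, and without WT female 3 it was 2.

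Averaged over the sexes, 6 genes rose and 2 fell in KO, and 7 of the 8 are those of the male comparison, which shares its libraries. Tmem254a (chromosome 14, 25923724 to 25928096), a transmembrane protein gene with 2 near copies, passed here: it fell from 77.2 ± 11.1 to 55.9 ± 9.62 CPM in males and from 81.1 ± 9.98 to 59.5 ± 3.83 CPM in females (log2 fold change -0.45, SE 0.07, adjusted p = 0.00425). All 12 KO libraries lay below the WT mean of their sex. Gm6768 rose by a log2 fold change of 3.38 and Gm48370 fell by 0.91 on the log2 scale. Of 271 tested genes within 20 Mb of Chat, 8 had an unadjusted p under 0.001, and 6 of these are genes called in some comparison (Duxbl1 in males only), whose position led to this count. Without the genes called in any KO comparison it was 2 of 265, against 18 of 17818 elsewhere. Genes that did not pass included Gse1 (0.38), Zfp960 (0.71), the adenylyl cyclase gene Adcy3 (0.42, SE 0.10), Atcay (0.27) and Wscd2 (0.51) on the higher side, with adjusted p-values of 0.244 to 0.423. Duxbl1 (-0.53), Il4 (-0.22), Igip (-0.23) and Plac9a (-0.38) were on the lower side, with adjusted p-values of 0.2 to 0.423. Chrna7, the alpha-7 nicotinic receptor gene (0.42, SE 0.12), Kcnh1 (0.56, SE 0.14) and Zic2 (-0.34, SE 0.10) passed adjusted over the list alone and not over all genes.

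With the preset correlation 5 lists passed in the average, and 0 did with an estimated correlation or with fry. All 73 ribosomal protein genes (median -0.10, adjusted p = 1.18e-07) and all 45 nuclear oxidative phosphorylation genes (median -0.09, adjusted p = 8.73e-05) had negative changes, among them Rps26 (-0.14) and Ndufs4 (-0.12). With an estimated correlation both had an adjusted p = 0.898. Mitochondrially encoded genes had a median of -0.13 (adjusted p = 0.00544; adjusted p = 0.898 with an estimated correlation) and fibroblast markers of -0.16 (adjusted p = 0.0246; adjusted p = 0.697 with an estimated correlation). Without WT male 2 the fibroblast list did not pass (median -0.12, adjusted p = 0.119), nor did the mitochondrially encoded list without KO female 2 (median -0.08, adjusted p = 0.142) or without WT female 1 and 2 (median -0.03, adjusted p = 0.687). Potassium channel genes were higher in 15 of 21 cases (median 0.09, adjusted p = 0.00233; adjusted p = 0.697 with an estimated correlation). The count of lists was 3 without WT male 2 and 8 to 10 without any 1 of WT male 4 (10), KO male 3 (9), WT female 1 (8), WT female 3 (10), WT female 4 (8), KO female 3 (10) and KO female 6 (9). It was 2 without WT female 1, WT female 2 and KO female 1 together.

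Whether the KO effect differed between the sexes was tested as an interaction. By edgeR 0 genes passed, with 980 at an unadjusted p under 0.05; DESeq2 called 7 and voom 0. The smallest p-values belonged to Trpm8 (-0.77, SE 0.17), Mpped1 (-0.62), Olfm3 (-0.60), Btbd19 (-0.95) and Bcl11b (-0.68) on the lower side in females, all with adjusted p = 0.457. On the higher side were Col11a2 (0.68), the neuropeptide gene Gal (2.15, SE 0.53), Rab37 (0.46), Arhgef37 (0.77) and Mthfs (0.70), with adjusted p-values of 0.457 to 0.741. Glycinergic and GABAergic markers formed the 1 list that passed with either correlation: the female effect was lower than the male effect in 8 of 9 genes (median -0.37, adjusted p = 0.000801; adjusted p = 0.0341 with an estimated correlation; fry adjusted p = 0.0111). Slc6a5 (-0.51, SE 0.14), Slc32a1 (-0.37), the GABA synthesis genes Gad1 (-0.39) and Gad2 (-0.45), and Pax2 (-0.74) passed adjusted over the list alone. Serotonergic markers, with Tph2 at 3.99 (SE 1.37) and Slc6a4, the serotonin transporter, at 4.81 (SE 1.77), had a median of 1.72 (adjusted p = 5.38e-05; adjusted p = 0.5 with an estimated correlation). KO female 6 stood apart for Tph2, at 66.2 CPM against at most 10.5 CPM in the other KO females. Its serotonergic mean was 1.80 against -0.98 to 0.35, which did not pass the test for a value far from the rest. Without KO female 6 the serotonergic median was 1.04 (adjusted p = 0.000188; adjusted p = 0.546 with an estimated correlation). Catecholaminergic markers had a median of 1.24 (adjusted p = 2.9e-05; adjusted p = 0.422 with an estimated correlation), and of 0.90 without KO female 6 (adjusted p = 2.63e-05; adjusted p = 0.416 with an estimated correlation). Mitochondrially encoded genes (median -0.35), potassium channels (-0.17), GABA and glycine receptors (-0.27) and synaptic vesicle genes (-0.10) also passed with the preset correlation, and had adjusted p-values of 0.5, 0.5, 0.5 and 0.727 with an estimated correlation. The mitochondrially encoded median was -0.24 without KO female 2 (adjusted p = 0.0014; adjusted p = 0.739 with an estimated correlation), and the list did not pass without WT female 1 and 2 (median -0.11, adjusted p = 0.122). Across tested genes not on the X and Y lists, the male and the female KO effects had a Pearson r of -0.05; genes are not independent replicates. Without WT female 3 the gene count was 2 and without WT female 4 it was 3, and the list count was 11 without WT male 2 or without WT male 4.

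Females were compared with males in each genotype. In WT, 17 genes rose and 30 fell in females, and in KO 25 rose and 26 fell. Of 41 lists, 14 passed in WT and 12 in KO with the preset correlation, and 4 in each with an estimated one. The WT rises include Gm10020, Gm3411, Gm3373 and Gm26630, which were high in WT female 1 and 2 and were chosen after their values were seen. The Y-linked genes were lower by at least 178-fold for Kdm5d and at least 252-fold for Eif2s3y in WT females, against a floor of 3 counts per library. In KO females the bounds were 153-fold and 167-fold. Uty had at most 2 counts in a female library, and Xist, which overlaps Tsix, had 0 counts in all libraries and is uninformative. X-linked genes that escape inactivation rose as a group: all 10 were higher in females in WT (median 0.36, adjusted p = 6.63e-12; adjusted p = 3.42e-05 with an estimated correlation) and in KO (median 0.41, adjusted p = 2.8e-15; adjusted p = 5.68e-06 with an estimated correlation). The histone demethylase gene Kdm6a rose from 21 ± 3.97 to 34.1 ± 5.18 CPM in WT (log2 fold change 0.70) and from 20.3 ± 1.90 to 35.6 ± 1.24 CPM in KO (0.81). Eif2s3x rose by 0.58 in WT and 0.41 in KO.

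Genes known to respond to glucocorticoids, a list that includes the X-linked Tsc22d3, were lower in females of both genotypes. All 17 of the list had negative changes in WT (median -0.75, adjusted p = 5.65e-21; adjusted p = 0.00175 with an estimated correlation) and in KO (median -0.58, adjusted p = 3.29e-15; adjusted p = 0.00899 with an estimated correlation). In WT 3 of them fell over all genes and 14 adjusted over the list alone; in KO the counts were 3 and 13. Sgk1, a kinase induced by corticosteroids, fell from 232 ± 65 CPM in WT males (n = 5) to 53.1 ± 7.1 CPM in WT females (n = 4), a log2 fold change of -2.13 (SE 0.38, adjusted p = 0.0183). In KO it fell from 157 ± 93.3 to 49.8 ± 11.1 CPM (-1.66, SE 0.32, adjusted p = 0.0362). All 4 WT females lay below every WT male for Sgk1, and 5 of 6 KO females below every KO male. Map3k6 fell by 1.39 on the log2 scale in WT and by 1.13 in KO. The cell cycle inhibitor gene Cdkn1a fell in WT (-1.23), and Tsc22d3, a mediator of glucocorticoid action, fell in KO (-0.33). Fkbp5, a cochaperone of the glucocorticoid receptor, had changes of -0.44 and -0.40 that passed only adjusted over the list alone. Lcn2 had at most 1 count in a WT female library and 10 in a KO female library, against 6 to 1211 in males, so its fitted value is not a bound. Ada, which breaks down adenosine, fell from 4.14 ± 1.18 to 1.21 ± 0.314 CPM in WT (-1.78, SE 0.28) and from 3.15 ± 1.17 to 1.52 ± 0.24 CPM in KO (-1.04, SE 0.23). Of the genes called in WT and in KO 18 were shared, all in the same direction, against 0.132 in draws that take genes as independent. The sex-linked genes among them are shared by construction. WT and KO libraries of a sex also share description numbers in part, so the overlap is not independent evidence of a sex effect. The 10 shared genes not linked to sex chromosomes were Ada, Sgk1, Map3k6, Etnppl, Adipor2, Klf13, Etv4, Ppp1r3g, Xdh and Gm19439. The 11 male libraries had a mean of -14.0 ± 6.67 and the 10 female libraries of 15.4 ± 18.3 on the first principal component, which held 15.4% of the variance. Hox genes of paralog groups 4 to 9, markers of position along the neuraxis chosen after the data were seen, had medians of -1.88 in WT and -0.56 in KO females against males (adjusted p = 0.203 and 0.645 with an estimated correlation). Each description number occurs in 1 sex only, so sex and number cannot be told apart.

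**Figure D4:**
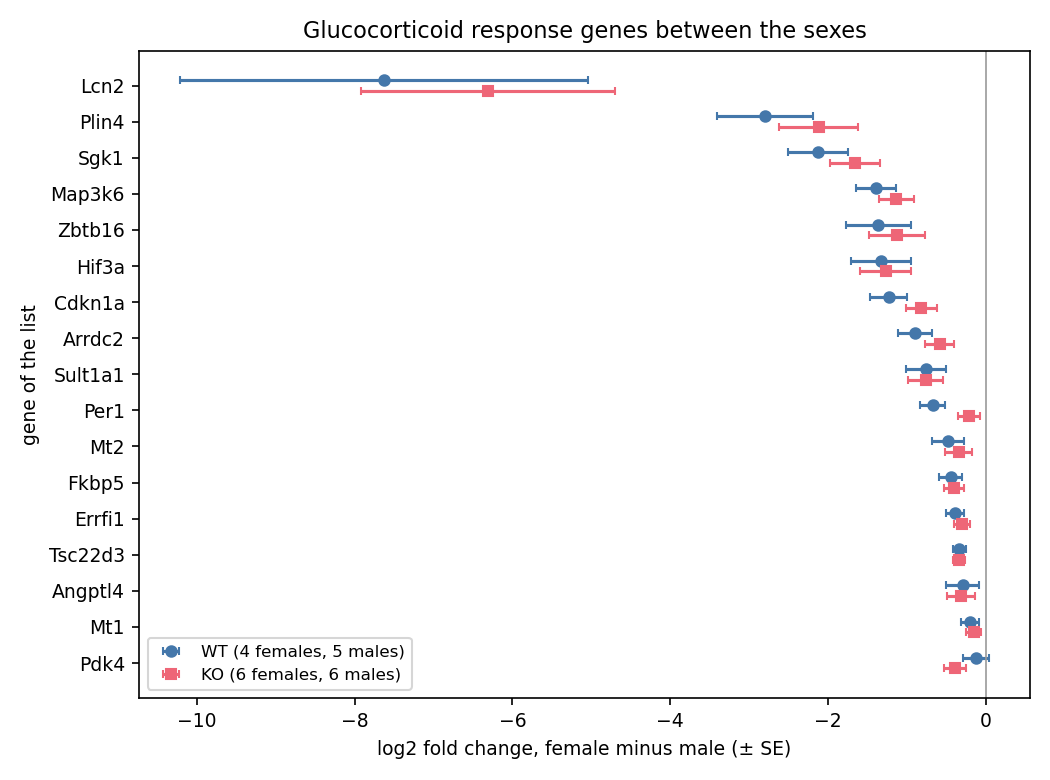
Log2 fold change of females against males (horizontal axis, ± SE) for the 17 genes of the glucocorticoid response list (vertical axis) in WT (circles, 4 females and 5 males) and in KO (squares, 6 and 6). All 34 estimates lie below 0; that of Lcn2 rests on at most 1 count per library in WT females.

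Other lists passed between the sexes in WT, in KO or in both, some with the preset correlation only. Heat shock and unfolded protein response genes were lower in females in all 26 cases in KO, where 4 fell over all genes: the chaperone genes Hspa1b (-1.72, SE 0.32) and Dnajb1 (-0.45), Xbp1 (-0.41) and Herpud1 (-0.32). The list had a median of -0.20 (adjusted p = 1.46e-14; adjusted p = 0.0799 with an estimated correlation; fry adjusted p = 0.00632) in KO, and of -0.17 in WT (adjusted p = 5.5e-08; adjusted p = 0.22 with an estimated correlation). Choroid plexus markers rose in WT females (median 0.48, adjusted p = 0.00312; adjusted p = 0.0283 with an estimated correlation), with Sostdc1 (1.77) past the threshold over all genes; in KO the median was 0.04 (adjusted p = 0.6), and a difference between the genotypes did not pass (interaction adjusted p = 0.0881). Glycinergic and GABAergic markers fell in KO females (9 of 9 lower, median -0.21, adjusted p = 0.00242; adjusted p = 0.021 with an estimated correlation). Interferon response genes were higher in 19 of 20 cases in WT (median 0.33, adjusted p = 4.2e-06; adjusted p = 0.0906 with an estimated correlation) and 16 of 20 in KO (median 0.16, adjusted p = 0.0177; adjusted p = 0.454 with an estimated correlation). Catecholaminergic and serotonergic markers had medians of -1.18 and -0.93 in WT (adjusted p = 1.77e-05 and 5.52e-05; adjusted p = 0.21 and 0.262 with an estimated correlation). In WT the cholesterol synthesis (-0.08), inflammation (-0.30), neuropeptide (-0.45), ribosomal (-0.10) and mitochondrially encoded (0.15) lists also passed, with adjusted p-values of 0.587, 0.0906, 0.236, 0.903 and 0.716 with an estimated correlation. Without WT female 1 and 2 the mitochondrially encoded list did not pass in WT (median -0.06, adjusted p = 0.881). In KO the synaptic vesicle (-0.14), potassium channel (-0.15), ribosomal (-0.09), mitochondrially encoded (-0.16), oxidative phosphorylation (-0.08) and GABA and glycine receptor (-0.13) lists did, with adjusted p-values of 0.243, 0.376, 0.804, 0.696, 0.804 and 0.685 with an estimated correlation. Without KO female 2 the mitochondrially encoded list did not pass in KO (median -0.03, adjusted p = 0.384). Motor neuron markers were higher in 11 of 14 cases in WT females (median 0.36, adjusted p = 0.0289; adjusted p = 0.59 with an estimated correlation). Named by the rule, Lrrc32 (0.76), Plxdc1 (0.70), Bcl11b (0.67) and Inka2 (0.55) rose in WT females, and Mettl24 (1.29), Col5a2 (0.98), BC024139 (0.84), Exd1 (0.74) and the DNA sensor gene Aim2 (0.59) rose in KO females. The WT count of 47 was 12 without WT female 1, WT female 2 and KO female 1 together, 25 without WT male 1, 29 without WT female 1 or 2, and 31 without WT female 3. The KO count of 51 fell to 17 without KO female 5, 21 without KO male 2, 22 without KO female 3, 24 without KO male 6, 26 without KO male 5, 27 without KO male 3, 28 without KO female 4, 29 without KO female 6 and 32 without KO male 1.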

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

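The tests of genes near Chat, of copies and their parent genes, of Cre in WT female 1 and 2, of the values in those libraries and of Gm6768, and the count of splits for the ribosomal and potassium channel lists, were chosen only after the result was seen. So were the list tests between the sexes, which show the glucocorticoid pattern, and the choice of the Hox genes; the tests that weigh that pattern and the other counts of splits were set before their own results were seen.

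Of the 9 genes called between KO and WT, 6 lie near Chat on chromosome 14 and the other 3 are near-identical copies of genes on that chromosome, and 5 (Gm10020, Gm6123, Gm3411, Gm3373, Gm26630) were as high in WT female 1 and 2 as in KO females. In these WT libraries 10 of 10 values of those 5 genes were at or above the lowest KO female. The genes were picked for being high there, so this count is no separate test. It shows only that high levels occurred without the knockout in these libraries. The margin was narrow in WT female 1 for Gm26630 (2.10 against 2.09 CPM) and Gm3373 (2.22 against 2.18 CPM). Exchanged labels are argued against by the highest Cre count of 0 in WT female 1 and 2. A candidate explanation is a stretch of chromosome 14 from another strain that is carried with the Chat allele and in part by WT female 1 and 2; it stays open, since no sequence was examined and without the called genes only 2 of 265 genes within 20 Mb of Chat had a p under 0.001 (18 of 17818 elsewhere, Fisher's exact test p = 0.0342), too few to decide. Reads moved from a parent gene to its copy also remain possible, since Ncoa4, the parent of Gm6768, had a log2 fold change of -0.17 (95% interval -0.32 to -0.02) where the reads gained by Gm6768 predict -0.25. Over all genes Ncoa4 did not pass (adjusted p = 0.936). Its interval held 0 in males (-0.32 to 0.10) and not in females (-0.46 to -0.01). For the other pairs, Rpl15 had -0.12 (interval -0.25 to 0.01, predicted -0.03) and Pdhb -0.13 (interval -0.25 to -0.004, predicted -0.06). For Gm6768 itself 0 WT libraries reached the lowest KO library, so an effect of the knockout and of such a stretch, if there is one, cannot be told apart, because it would be carried with the allele.

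In males, 71 of 73 ribosomal protein genes had negative and 15 of 21 potassium channel genes had positive changes in KO, which may reflect variation between libraries that the groups do not explain. The same opposition, with both lists past the test in opposite directions, occurred in 27 of 100 splits of the 11 males. The 1 split that called 912 genes had 56 of 73 ribosomal protein genes (median 0.37) and 36 of 45 oxidative phosphorylation genes (median 0.36) past the threshold and a median of -0.22 for potassium channels. Within groups, the means of the ribosomal and the potassium channel list had a Pearson r of -0.75 over the 21 libraries (permutation p = 0.0013, Spearman rho -0.69, p = 0.00403, r = -0.62 without the 2 farthest libraries; adjusted p = 0.0013 in a family of 3 relations). An effect of the knockout on these lists stays open beside this variation.

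Glucocorticoid response genes were lower in females of both genotypes, by 0.98 on the log2 scale in the mean of the list. A different position of the punch along the neuraxis is argued against as the whole cause, as far as the mean of 6 Hox genes tracks it. With that mean as a covariate the list kept an adjusted p of 0.00424 with an estimated correlation in WT (median -0.68). Position in other directions was not tested. Leaving out each library in turn gave adjusted p-values of 7.53e-05 to 0.00696 in WT and 0.000746 to 0.022 in KO, and without WT female 1, WT female 2 and KO female 1 together they were 0.0106 and 0.0263. Handling or collection that follows the description numbers cannot be told apart from sex, because no number occurs in both sexes; the means of the number sets ranged by up to 0.642 within a sex. A difference in hormone state between the sexes, which the design names only as sex, also stays open and was not tested.

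Other splits of the samples into groups of the same sizes were counted, 100 for each result with the real one included, out of 462 for males, 210 for females, 97020 for both sexes, 126 for WT and 462 for KO. Fewer than 5 of 100 splits were as large for the number of genes called in the average (8 real, 3 of 100). This was also so between the sexes in WT (47 real, highest other 3, 1 of 100) and in KO (51 real, highest other 17, 1 of 100). These shares were not adjusted for the number of results weighed. Between the sexes, the Y-linked genes follow the real split by construction, and the counts do not tell sex from description number. For the average, the highest other split called 852 genes. All 8 genes of the real count are on chromosome 14 or are close copies of genes there. Among them are the 5 that were as high in WT female 1 and 2 as in KO females. The share for the average thus does not tell an effect of the knockout from DNA carried with the Chat allele. Chance cannot be excluded for the number of genes called in males (8 real, highest other 912, 5 of 100) or females (1 real, highest other 287, 11 of 100). This concerns the counts and not single genes, such as Gm6768, which separated all 12 KO from all 9 WT libraries (adjusted p = 1.15e-11 in males). The highest splits in males, in females and in the average called many times the real count, while the median of the other splits was 0 genes in each. Such splits point to a structure of the samples that the groups do not explain. Deviations from the group means were correlated between KO and WT libraries of a sex. In males the mean r was 0.062 for pairs of the same description number and -0.018 for other pairs. In females it was 0.027 and -0.010. These means were given no p-value, so whether the structure follows the description numbers stays open. In the female split that called 287 genes, 1 of the 3 numbers was kept together and 2 were divided. For the interaction 0 genes were called by edgeR (980 at an unadjusted p under 0.05, DESeq2 7, voom 0), the highest other split called 173, and 100 of 100 were as large. For lists, chance cannot be excluded in males (12 real, highest other 15, 6 of 100), females (4 real, 13, 83 of 100), the average (5 real, 16, 71 of 100), the interaction (7 real, 15, 53 of 100), or between the sexes in WT (14 real, 18, 13 of 100) and in KO (12 real, 19, 30 of 100). It cannot be excluded for the correlation of the male and female effects either (r = -0.05 real, highest other 0.26, 61 of 100).

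Of 153 groups of libraries tested for a value far from the rest, 8 had one, where chance gives 7.65. Chat was at 30.5 CPM in KO male 6, Gm6768 at 11.8 CPM in KO female 2, Tmem254a at 66.9 CPM in KO female 3 and Ada at 1.06 CPM in KO female 5, each far from the other libraries of its group. KO female 6 stood apart for Tph2 (66.2 CPM) and Ddc (36.8 CPM). WT male 4 stood apart for the mean of the serotonergic list (-0.31). Ddx3y in KO female 5 was at 0.0367 CPM, a single count. Cre, which no comparison used, had at least 27 counts in each KO library and 0 in each WT library.

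The KO effect differed between females and males for 7 lists by the interaction test with the preset correlation. The adjusted p-values were 2.9e-05 for catecholaminergic markers, 2.9e-05 for mitochondrially encoded genes, 5.38e-05 for serotonergic markers, 0.000801 for GABA and glycine receptors, 0.000801 for glycinergic and GABAergic markers, 0.00491 for potassium channels and 0.0167 for synaptic vesicle genes. With an estimated correlation only the glycinergic and GABAergic markers passed among these 7 (adjusted p = 0.0341).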

How the results depend on the processing

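Fits without WT female 1, WT female 2 and KO female 1, with the motor neuron list as a covariate, the ratio of Chat to Slc5a7, the list tests between the sexes and those without KO female 6, WT male 2, KO female 2, WT male 4 or WT female 1 and 2 were chosen only after seeing the data; the other alternatives were set before. Apart from left-out libraries, 167 of 218 values that answer a comparison kept their direction and their side of the threshold or stayed within the spread or 1.5 times the count, 45 moved and 6 no longer passed; 0 that had passed changed sign, while Chat in males, which had not passed, did in 6 of those 45. The cause was not tested unless stated. Of the 51 named values that passed, 1602 of 1794 alternatives kept the call, 192 lost it and 0 changed sign; of the 172 that did not pass, 28 alternatives changed sign and 81 passed.

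Gene counts in males were 23 with DESeq2, 19 with voom, 22 with 2 surrogate variables and 13 at an adjusted p under 0.1; in females the count was 4 without WT female 1, WT female 2 and KO female 1. Interaction counts were 1 without a filter, 7 with DESeq2 and 1 at an adjusted p under 0.1. Between the sexes, DESeq2 called 133 in WT and 164 in KO, voom 84 and 110, an adjusted p under 0.1 gave 88 and 94, a fold threshold of 1.2 gave 13 and 7 (a stricter test by construction), and the compared groups alone 84 and 23. WT counts between the sexes were 12 without WT female 1, WT female 2 and KO female 1, and KO counts were 33 with the replicate block, although the replicate numbers did not pair the libraries (mean r of -0.00663 in males and 0.0223 in females between libraries of the same number).

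List counts were 0 in males, 0 in females, 0 in the average, 1 in the interaction and 4 in each sex comparison with an estimated correlation between genes; with the fry rotation test they were 1, 0, 0, 1, 6 in WT and 5 in KO. Among other settings they were 8 in the average without a filter, 2 in females with the replicate block, 6 in males with the description number block, 2 in females and 13 in the interaction with 2 surrogate variables, and 8 in females and 2 in the average without WT female 1, WT female 2 and KO female 1.

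Chat in males, near 0, changed sign with RLE normalization (0.000879), DESeq2 (0.0031), the description number block (0.18), the library size without mitochondrial, haemoglobin and ribosomal RNA genes (0.000149), without WT female 1, WT female 2 and KO female 1 (0.00791) and with only the groups compared (0.00626). Its adjusted p stayed at 0.775 to 1 over the alternatives, and at 0.695 to 1 in females and 0.529 to 1 in the average. Chat relative to Prph in place of Slc5a7 was -0.13 in males, -0.35 in females and -0.24 in the average; relative to Phox2b it was -0.15 in females and -0.41 in the average, and relative to the motor neuron list -0.18 in males, and each of these lost the call.

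Leaving out each library in turn gave Chat changes of -0.43 to 0.16 in males, -0.60 to -0.19 in females and -0.45 to -0.10 in the average. Chat relative to Slc5a7 ranged from -0.65 to -0.48 in males, -0.53 to -0.30 in females (8 of 10 lose the call) and -0.55 to -0.43 in the average. The correlation of the male and female effects ranged from -0.0893 to 0.0490, and changed sign without WT male 3 (0.0235) and without KO female 6 (0.0490). Gene counts ranged from 6 to 24 in males (24 without KO male 3), stayed at 1 in females, and ranged from 7 to 12 in the average, 0 to 3 in the interaction, 25 to 60 between the sexes in WT and 17 to 59 in KO. List counts ranged from 7 to 15, 2 to 6, 3 to 10, 6 to 11, 11 to 16 and 9 to 18 in the same order. Depth limits genes such as Ren1, with 0 to 5 counts per library.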

Other observations

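All tests here on the Hox genes, on Cre with gene lists and on the ratio of Chat to Slc5a7 with its denominators were chosen only after the result was seen; the test of Cre against that ratio was set before its own result was seen. Across the 12 KO libraries, Cre transcript was higher where the brainstem motor neuron markers were higher. The Pearson r of log2 Cre CPM and the mean of the motor neuron list was 0.897 (permutation p = 8e-05, adjusted p = 0.00336 in a family of 42 relations) and Spearman's rho was 0.902 (adjusted p = 0.00546). Without the 2 libraries farthest from the median r was 0.860, and it was 0.816 in the 6 males and 0.998 in the 6 females. The cholinergic machinery followed with r = 0.865 (adjusted p = 0.00609; rho = 0.867, adjusted p = 0.0124; 0.865 without the 2 farthest), and the next list, pericytes and smooth muscle, had r = 0.717 (adjusted p = 0.144). Cre may thus be transcribed in motor neurons that vary in number between punches, a hypothesis that other cells rich in the same punches would also meet.

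Chat counts relative to Slc5a7 counts, genes that cholinergic neurons both express, were lower in KO. The ratio was 0.450 ± 0.0544 in WT males (n = 5) and 0.306 ± 0.0613 in KO males (n = 6), a log2 difference of -0.57 (exact permutation p = 0.00649 over 462 arrangements). In females it was 0.410 ± 0.0804 in WT (n = 4) and 0.310 ± 0.0502 in KO (n = 6), a log2 difference of -0.40 (exact permutation p = 0.0476 over 210 arrangements). The female result did not pass when any 1 library other than WT female 1 (-0.53) or KO female 6 (-0.47) was left out; it was -0.41, -0.35 and -0.30 without WT female 2, 3 and 4, and -0.40, -0.35, -0.35, -0.38 and -0.42 without KO female 1 to 5. Averaged over the sexes the difference was -0.48, or -28.5% (permutation within sex, exact p = 0.000577 over 97020 arrangements). These permutations did not hold the description number fixed. WT male 1 to 4 (0.425 to 0.514) share a number with KO male 3 alone, which was lower (0.323). WT male 5 (0.380) lay within the KO males of its number (0.324 to 0.390). KO male 1 and 2 had the lowest ratios (0.219 and 0.252) and a number without WT males. Genotype and number are thus told apart only in part in males. In males Chat was at 13.3 CPM in WT and in KO and Slc5a7 at 29.2 and 44.3 CPM, but without KO male 6, which had 30.5 CPM of Chat, the KO means were 9.83 and 34.4 CPM (n = 5). Which of the genes carries the male difference thus depends on that library, without which the ratio still differed (-0.59). A loss of Chat transcript in part of the cholinergic neurons is a candidate explanation that these levels do not single out, and with Prph, a filament gene of peripheral and motor neurons, as the denominator the difference was -0.24 and did not pass. No relation of Cre with the ratio was detectable across the 12 KO libraries (r = -0.0242, permutation p = 0.941; rho = -0.0769, p = 0.817; adjusted p = 0.941). This leaves the cause open, because Cre also rose with the motor neuron markers.

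Hox genes of paralog groups 4 to 9, whose expression marks position along the hindbrain and spinal cord, were lower in females in all 6 tested cases. In WT the median log2 fold change was -1.88, with Hoxb8 at -5.00 and Hoxa7 at -2.14 (adjusted p = 1.29e-05; adjusted p = 0.203 with an estimated correlation). In KO the median was -0.56 (adjusted p = 0.0206; adjusted p = 0.645 with an estimated correlation). Punches from females taken nearer the rostral end could give this pattern, but the smaller of the 2 adjusted p-values with an estimated correlation, 0.203, keeps it open.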
